A study of Sus scrofa with 6 samples.

How the data were processed

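Chromatin accessibility was measured by ATAC-seq (assay for transposase-accessible chromatin with sequencing), in which the Tn5 transposase cuts and tags open DNA, in porcine (Sus scrofa) intestinal epithelial cells. The labels give 6 libraries, 3 from control cells and 3 from cells stimulated with deoxyshikonin, a naphthoquinone of the shikonin family. Dose and duration of treatment are not given in the sources used here. Per the labels' protocols, cells were lysed, transposed and made into libraries with a Vazyme TruePrep kit, followed by size selection. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

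The deposited data are 6 peak lists in the narrowPeak layout. Per the submitters' processing notes the tools were bcl2fastq 2.17, Trim Galore 0.6.6, Bowtie2 2.4.2, MACS2 2.1.0 and deepTools. Their settings are not given in the sources used here. Each list belongs to 1 library, so peaks were called per library and not on pooled reads. For each peak the authors deposited a fold enrichment over the peak caller's local background (a ratio), a −log10 p and a −log10 q, a whole-number score that is 10 times the −log10 q, and the summit position. These are the authors' values, and they describe a peak within its own list. The lowest −log10 q lay between 2.00 and 2.09 in the 6 lists, and no peak was narrower than 200 bp.

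Coordinates are on contigs whose names begin with LUXX01. The genome build is not given in the sources used here, and no sequence or annotation of it was used. Gene names of another pig assembly could not be tied to these contigs. Promoter shares, promoter gains per gene, the gene lists (host defense peptides, epithelial junctions, stress responses, markers of other cell types and others) and the motif comparison were all fixed before the data were examined and could not be made. Regions are therefore given by contig and position (counted from 1), without genes.

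Total read numbers are unknown. Relative depth was solved from the peak values. With no control sample, MACS2 gives the fold enrichment as (pileup + 1) / (background + 1) at the summit and the p as a Poisson tail, so each peak's pair of values fixes its pileup of tags and its background. The solution matched the deposited p within a relative 0.0001 for 100% of peaks in every list, and simulated peaks were recovered exactly (100% of 3728). The lowest background of a library is its genome-wide mean pileup, which is proportional to its number of tags where all lists used the same tag length and genome size. Local backgrounds were whole multiples of 0.02 in 100% of cases in every list, which corresponds to tags extended to 200 bp and counted over 10000 bp in all 6 lists. This is the depth measure used here. Duplicate reads are not independent molecules, so any precision taken from these tag numbers covers counting error only.

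Peaks of the 6 libraries were merged into 1 region where they overlapped by at least 1 bp. A region was present in a library if a peak of that library fell in it. Gained regions were present in 3 of 3 deoxyshikonin and 0 of 3 control libraries, and lost regions the reverse. No test of presence per region was made, since 3 libraries against 3 cannot give a two-sided exact p under 0.1. Group values were compared by exact permutation tests over all 20 arrangements, two-sided, with the same limit. Agreement of lists was measured by the Jaccard index of base pairs, the shared length over the combined length. The regions named in the text are the 5 gained and 5 lost with the highest mean percentile of −log10 q within the 3 lists that hold them, a rule set before the data were examined. The fixed alternatives were peaks with −log10 q of at least 5, lists of equal length (the 17169 best peaks of each library), 50% coverage as presence, windows of 100 bp either side of the summit, a clear distance of 500 bp, leaving out each library, and the replicate number as a block.

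Further comparisons were added after the data were examined. Summit pileup over library background ("height") was compared at regions present in all 6 libraries. Log2 heights were centred on each library's median and tested with limma (trend, Benjamini-Hochberg). Heights were simulated for the 13209 regions with an assumed spread between replicates, 100 regions changed at each of 2 folds and the rest unchanged. There limma recovered 12% of regions changed 1.5-fold and 73% of those changed 2-fold, with 4 false calls. Recovery after adjustment depends on the share of regions that change and on the spread, so these values do not give the sensitivity in the real data. Positions were compared by shuffling region classes 1000 times and by resampling contigs 1000 times. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.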

Results

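ATAC-seq peak lists were compared between control porcine intestinal epithelial cells and the same kind of cells stimulated with deoxyshikonin, with 3 libraries in each group. The comparison asks which stretches of chromatin open or close when the cells are stimulated. The control lists held 21404, 17169 and 25888 peaks for replicates 1 to 3, and the deoxyshikonin lists held 35784, 33295 and 39281. The relative depth of a library, given as its genome-wide mean tag pileup, was 1.89, 2.13 and 2.57 in the controls and 2.06, 1.46 and 1.96 under deoxyshikonin. All positions below are on contigs of an assembly that the sources used here do not name, so regions carry no gene, exon or promoter annotation.

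Called accessible regions were more numerous in the deoxyshikonin libraries and covered more sequence. The deoxyshikonin lists held 36120 ± 3007 peaks (SD, n = 3) against 21487 ± 4360 in the controls (SD, n = 3), a ratio of 1.68. The covered length was 16.6 ± 1.29 Mb under deoxyshikonin (SD, n = 3) and 10.2 ± 2.77 Mb in the controls (SD, n = 3), a ratio of 1.62. All 3 deoxyshikonin libraries exceeded all 3 controls in both measures, and the lowest deoxyshikonin list was 1.29 times as long as the longest control list. The two-sided exact permutation p was 0.1 for peak number and for covered length, which is the smallest p that 3 libraries against 3 can give. At the similar q limit of the lists, the lowest −log10 p was 4.09 to 4.15 under deoxyshikonin and 4.23 to 4.54 in the controls. No comparison at a common p limit was run. Over whole lists, which hold different regions, the median peak width was 392 ± 19.8 bp under deoxyshikonin and 407 ± 28.1 bp in the controls (SD, n = 3 each, exact permutation p = 0.6). The median fold enrichment was 5.38 ± 0.227 and 5.43 ± 0.173 (SD, n = 3 each, exact permutation p = 0.9). Mean depth was lower in the deoxyshikonin libraries, at 1.83 ± 0.319 against 2.20 ± 0.344 (SD, n = 3 each, exact permutation p = 0.4). The shallowest library of the series, deoxyshikonin replicate 2, held more peaks than the deepest, control replicate 3. In a comparison added after the data were examined, the median summit pileup over library background, at regions present in all 6 libraries, was 19.4 ± 1.85 under deoxyshikonin and 16.1 ± 2.16 in the controls (SD, n = 3 each, exact permutation p = 0.1). It was 17.5, 21.2 and 19.4 in deoxyshikonin replicates 1 to 3, and 17.5, 13.6 and 17.1 in control replicates 1 to 3.

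**Figure D1:**
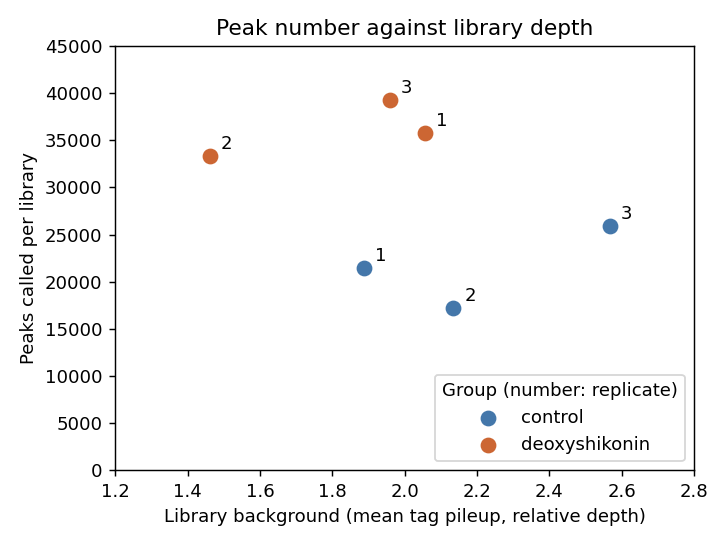
Peaks called per library (vertical axis, number of peaks) against the library background (horizontal axis, mean tag pileup, a measure of relative depth), with 1 point per library and the replicate number beside it. The 3 deoxyshikonin libraries lie between 33295 and 39281 peaks and the 3 controls between 17169 and 25888, while the depths of the groups overlap.

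Most chromatin that was accessible in the controls stayed accessible, and the deoxyshikonin libraries added a large further set of regions. Merging all peaks gave 51099 regions. Of the 14403 regions present in all 3 control libraries, 13209 (91.7%) were also present in all 3 deoxyshikonin libraries and 185 (1.28%) were in none of them. Of the 24953 regions present in all 3 deoxyshikonin libraries, 52.9% were present in all 3 controls and 6065 (24.3%) were in none. Gained regions thus numbered 6065 and lost regions 185, so that 97.0% of the regions that separated the groups fully were gained. Absence here means that no peak was called. A further 5679 regions were present in all 3 deoxyshikonin libraries and in 1 or 2 controls, against 1009 present in all 3 controls and in 1 or 2 deoxyshikonin libraries. Regions seen in 1 library only made up 28.5% of all regions, 11919 of them in a deoxyshikonin library and 2657 in a control. When every list was shortened to its 17169 best peaks, 1276 regions were gained and 788 lost, and the share of gained regions among them fell to 61.8%. Lists of equal length hold the number of peaks fixed, so they cannot show a change in that number.

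**Figure D2:**
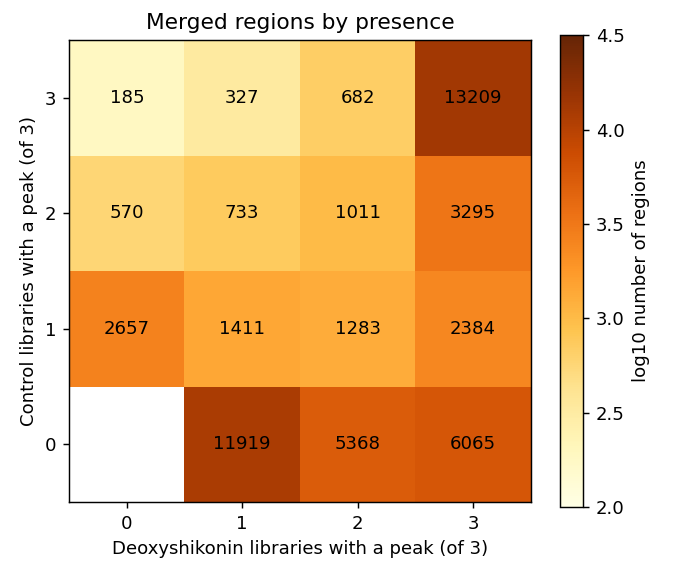
Number of merged regions by the number of deoxyshikonin libraries (horizontal axis, 0 to 3) and control libraries (vertical axis, 0 to 3) that hold a peak in them, with colour on a log10 scale. The corner of gained regions (3 deoxyshikonin, 0 control) holds 6065 and the opposite corner of lost regions holds 185, while 13209 regions are present in all 6 libraries.

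Gained regions were narrower and weaker than the regions shared by all libraries, though some ranked among the best peaks of their lists. The median width of their peaks was 374, 345 and 359 bp in deoxyshikonin replicates 1 to 3, against 647, 576 and 599 bp for peaks of the same lists at regions present in all 6 libraries. Within the deoxyshikonin lists, the median gained peak stood at the 42.0, 40.1 and 44.2 percentile of −log10 q in replicates 1 to 3, and the median peak at a shared region at the 79.3, 77.4 and 81.1 percentile. The definitions favour such a difference, since weak peaks are missed more readily and a call in all 6 libraries favours strong ones. The highest-ranked gained region lay on contig LUXX01054881.1 at 4247818 to 4248749, with an authors' fold enrichment of 8.30 ± 0.305 (SD, n = 3). The next was on LUXX01077104.1 at 449061 to 449999, where the fold enrichment was 8.55 ± 0.281 (SD, n = 3). The strongest enrichment among the 5 named gained regions, 11.7 ± 0.633 (SD, n = 3), was on LUXX01056594.1 at 20100 to 20939. The region on LUXX01089374.1 at 2608453 to 2609086 had 8.62 ± 0.369, and a second region of LUXX01077104.1, at 2738852 to 2739704, had 10.7 ± 1.92 (SD, n = 3 each). The lowest percentile of any of these 5 in a deoxyshikonin list was 91.1. No control library had a peak in, or within 500 bp of, any of these 5 regions.

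Lost regions were few, weak and often on contigs with hardly any other region. The median width of their peaks was 267, 265 and 327 bp in control replicates 1 to 3, and their median peak stood at the 28.1, 26.3 and 32.3 percentile of −log10 q in control replicates 1 to 3. As with gained regions, the definition favours weak peaks. Of the 185, 61 (33.0%) lay on contigs that held at most 2 regions, against 7.35% of the regions present in all 6 libraries and 2.03% of the gained regions. The odds ratio of lost against shared regions was 6.20 (Fisher's exact test, two-sided, p = 1.21e-23, across regions, which are not independent replicates), a test chosen after the positions of the lost regions had been seen. Among the 5 named lost regions, 3 began within the first 20 bp of a contig: LUXX01101386.1 at 16 to 243, LUXX01054784.1 at 1 to 296 and LUXX01087214.1 at 19 to 282. Their authors' fold enrichments in the controls were 13.3 ± 0.795, 9.65 ± 0.949 and 8.95 ± 1.47 (SD, n = 3 each). The other two lay inside long contigs. The region on LUXX01077477.1 at 1544227 to 1544979 had a fold enrichment of 6.29 ± 0.288 and that on LUXX01073274.1 at 2139872 to 2140240 had 6.96 ± 1.17 (SD, n = 3 each). The count of lost regions rose to 341, 554 and 240 without control replicates 1, 2 and 3. It rose to 284, 230 and 375 without deoxyshikonin replicates 1, 2 and 3. Fewer libraries then have to meet the criterion, which favours a rise in each case. Why the rise differed between libraries was not tested.

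The peak lists grouped by treatment. The Jaccard index was 0.556 ± 0.044 between control libraries and 0.577 ± 0.00449 between deoxyshikonin libraries (SD over 3 pairs each), and 0.434 ± 0.0503 between the groups (SD over 9 pairs). The highest index between groups, 0.491, was below the lowest within a group, 0.509. Unequal covered lengths cap the index, which can lower it between groups. In lists of equal length the means were 0.592, 0.605 and 0.499, in the same order. There the highest index between groups was 0.538 and the lowest within a group 0.569. No p is given, because pairs share libraries.

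Gained regions were spread over 1217 of the 4046 contigs that held any region, and their share of gained plus shared regions differed between contigs. Among the 257 contigs with at least 60 regions, the gained share of gained plus shared regions was 30.1%, and it ranged from 4.55% to 73.1% between contigs. Its SD over contigs was 14.0 percentage points, against a mean of 7.89 and a highest value of 9.15 in 1000 shuffles of the region classes over these contigs (permutation p = 0.001, the smallest that 1000 shuffles can give). The highest share was on LUXX01071078.1, with 19 gained and 7 shared regions, followed by LUXX01102040.1 with 18 and 8. The contig richest in regions, LUXX01096074.1, had 9 gained and 164 shared regions. The share depends on the number of shared regions as well, so its spread does not show crowding of gained regions. Per Mb up to a contig's last region, gained and shared regions correlated at a Spearman rho of 0.119 over the 257 contigs (permutation p = 0.061). The densest groups of gained regions within 100 kb held 6 each, on LUXX01015702.1 at 5557468 to 5646674 and on LUXX01022101.1 at 971789 to 1070851, and neither stretch held a region present in all 6 libraries. The contigs and clusters named here, the shuffling test and the correlation were chosen after the data were examined.

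**Figure D3:**
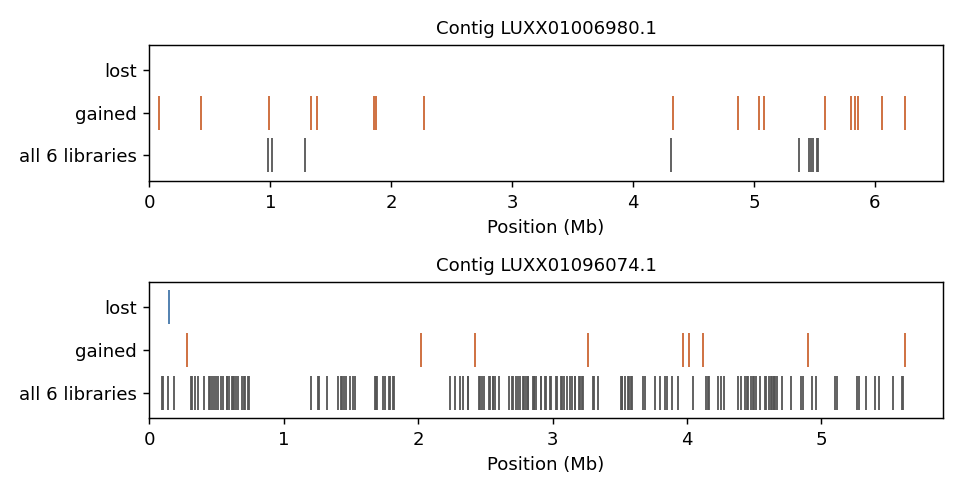
Positions (horizontal axis, Mb) of regions present in all 6 libraries, gained regions and lost regions on a contig with a high gained share (LUXX01006980.1, 18 gained and 10 shared regions) and on a contig with a low one (LUXX01096074.1, 9 gained and 164 shared regions). Each vertical line is 1 region.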

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

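The alternatives that restrict contigs, leave out both libraries numbered 2 or concern heights were chosen after seeing the data, and the others before. The direction of the difference in peak number, covered length and depth was kept under every alternative run. The log2 ratio of peak number was 0.77 and lay between 0.61 and 0.91 when each library was left out in turn, and the log2 ratio of covered length was 0.73 and lay between 0.54 and 0.93. In equal lists the log2 ratio of covered length was 0.22 (exact permutation p = 0.3). No permutation p in these comparisons can pass 0.05. Gained regions (6065) numbered 6181 to 8458 and lost regions (185) 230 to 554 when each library was left out in turn. Equal lists gave 1276 gained and 788 lost regions, and 862 and 72 when a region also had to be absent from the full lists of the other group. Equal lists drop the weaker peaks of the longer lists, which can end gained calls and create lost ones, and the added requirement can only lower both counts. Summit windows gave 285 lost regions, and the cause was not tested. Contigs with at least 60 regions, a subset by construction, held 3097 gained and 73 lost regions. Without both libraries numbered 2, when fewer libraries have to meet the criterion, 691 regions were lost. Equal lists lowered the difference between the mean Jaccard index within and between groups from 0.133 to 0.0989. Unequal covered lengths cap the index in full lists, and how much of the change this explains was not tested. With a replicate block, regions that moved the same way in at least 2 of 3 numbers and never the other way numbered 13817 gained and 1082 lost, a looser criterion. With the block, 856 shared regions were called higher and 981 lower, against 882 and 1018 without it. The numbers showed no clear pairing of the libraries. Deviations in presence from the group means correlated at −0.000286 to 0.0146 between libraries of the same number and at −0.0134 to 0.0114 between different numbers. Control replicates 1 and 3 correlated best with the deoxyshikonin library of their own number, and control replicate 2 with deoxyshikonin replicate 1. Correlations this small cannot exclude a pairing. None of the 10 named regions had a peak of the other group within 500 bp, and the stricter threshold and equal lists could not test them, since they were chosen for high ranks. The height calls at shared regions (882 higher, 1018 lower) became 1667 higher and 72 lower when scaled by depth alone, and 271 and 397 with the peak caller's fold enrichment as height, the cause of which was not tested. They ranged from 547 to 746 higher and from 654 to 843 lower when each library was left out in turn, and were lowest without deoxyshikonin replicate 2. Promoter shares, promoter gains and losses, gene lists and motifs were not run, because no annotation or sequence of the contigs was used. The total number of reads is unknown, and a region that is absent from a list was not called at that library's depth, which is not evidence of closed chromatin.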

Other observations

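The tests of heights (their splits included), background ratios over contigs, neighbouring regions, contigs with few regions, predicted passing of the threshold and absence from held-out libraries were chosen after the data had been seen, while those of depth, equal lists and splits of gained regions were chosen when only the sizes of the peak lists were roughly known. At the 13209 regions present in all 6 libraries, peak heights, which rest on pileups solved from each list and not on deposited pileups, also differed between the groups. After libraries were centred on their median height, 882 regions were higher and 1018 lower under deoxyshikonin (limma, Benjamini-Hochberg adjusted p below 0.05, n = 3 per group), or 14.4% of them. The median change was 0.60 on the log2 scale among the higher and −0.57 among the lower. The largest increase was on LUXX01046077.1 at 29526 to 30645, with a log2 change of 1.61 (SE 0.187, limma adjusted p = 1.05e-10). Its height was 0.386 to 0.455 of the library median in the 3 controls and 1.13 to 1.42 in the 3 deoxyshikonin libraries. The largest decrease was on LUXX01082911.1 at 2670755 to 2671484, with a log2 change of −1.25 (SE 0.207, limma adjusted p = 2.69e-06). Both regions were chosen after their values were seen. Before centring, shared regions stood 0.25 higher in log2 height under deoxyshikonin, and scaling by depth alone gave 1667 higher and 72 lower. The balance of higher and lower regions thus rests on the scaling. It also rests on the required call in all 6 libraries. That leaves out 6065 gained regions and 5679 present in all 3 deoxyshikonin libraries and 1 or 2 controls. The other way, 185 lost regions and 1009 present in all 3 controls and 1 or 2 deoxyshikonin libraries are left out. Log2 heights correlated at a mean of 0.88 within groups and 0.78 between groups, across regions, which are not independent replicates. With deoxyshikonin replicate 2 left out, 547 were higher and 654 lower.

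The 6 libraries can be split into equal groups in 10 ways, too few for a share under 0.05. The real split, 1 of the 10, gave 6065 gained regions, and the highest count on either side of any other split was 462. For heights the real split, again 1 of the 10, gave 1900 regions by limma. The other splits gave at most 0 regions past the adjusted threshold and 259 to 451 at an unadjusted p under 0.05, against 3505 for the real split. Every other split mixes the treatments, so a group difference of any origin widens the spread within its groups. Low counts in those splits, for gained regions and for heights, are therefore partly built in.

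The longer deoxyshikonin lists might come from depth, from a better signal over background, or from more open chromatin. Depth is argued against, since the ratio of mean depth, deoxyshikonin over control, was 0.831 and stayed between 0.777 and 0.914 when any 1 library was left out. Median heights at shared regions were 19.4 ± 1.85 under deoxyshikonin and 16.1 ± 2.16 in the controls (SD, n = 3 each, exact permutation p = 0.1, the smallest possible). Deoxyshikonin replicate 1 and control replicate 1 stood at the same 17.5, with depths of 2.06 and 1.89, and held 35784 and 21404 peaks. This is 1 pair of libraries picked for its match, over regions that had to be called in both. It does not decide on signal over background. Heights were then scaled to equal medians. Regions that a pair of deoxyshikonin libraries predicted to pass the threshold were absent from a control library in 29.6% to 34.3% of cases. They were absent from the remaining deoxyshikonin library in 5.93% to 11.8%. Regions predicted from a pair of controls were absent from the remaining control in 1.52% to 12.4% of cases. From a deoxyshikonin library they were absent in 3.37% to 10.5%. The first excess was set as evidence against signal over background, but it cannot decide. The scaling rests on regions called in all 6 libraries, which favours regions high in the shorter control lists. For gained regions as a whole, signal over background also stays open. From mean heights 60.2% were predicted to pass in all 3 controls, above the bound of 50% set before this value was seen as evidence against it, but that bound ignored that gained regions were selected for being called in the very libraries whose heights make the prediction, and from the lowest of their 3 heights 30.0% were predicted to pass. Gained regions made up 4.57% of all merged regions in equal lists and 11.9% in full lists. The ratio of these shares, 0.385, lay between the bounds set for either reading of weak peaks or deeper calling. A change of chromatin under deoxyshikonin stays among the open explanations.

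Gained regions lay beside each other more often than their number on each contig gives. The nearest neighbour of a gained region, among gained and shared regions, was also gained in 44.3% of 5900 cases, against a mean of 38.2% and a highest value of 40.1% in 1000 shuffles within contigs (permutation p = 0.001, the smallest these can give). The gained share of contigs did not rise with the ratio of local background, deoxyshikonin over control (Spearman rho −0.136 over 257 contigs, permutation p = 0.033). A rise had been predicted if copy number were the cause of its spread over contigs. A lower regional background under deoxyshikonin would ease calling there and give a negative rho, which could hide such a rise. Both explanations therefore stay open. Whether the gained share follows the level of local background itself, and not its ratio, was not tested. On LUXX01026070.1 and LUXX01034846.1, which had the lowest share, local background was 3.25 and 2.26 in control replicate 1, and 2.89 and 2.21 in deoxyshikonin replicate 1. On LUXX01071078.1 and LUXX01102040.1, which had the highest, it was 1.93 and 1.47 in control replicate 1, and 1.68 and 1.16 in deoxyshikonin replicate 1. Weak peaks falling in peak-poor stretches also stay open. In equal lists, at least 50 kb from the start of the contig and from the end of its last region, gained regions had 0.486 and lost regions 0.936 regions present in all 6 lists within 50 kb, a difference of −0.450 (95% contig bootstrap interval −0.556 to −0.337), but the sets are not alike: 72 of the 788 lost regions were absent from the full lists of the other group, against 862 of the 1276 gained, so most of the lost ones had only dropped in rank, and the median percentiles were 30.8 and 38.6. The definition of this test was revised 3 times after its values had been seen. The earlier definitions, which counted regions of the full lists, gave −0.998, −0.506 and −0.756, and the last one over all positions gave −0.285 (interval −0.378 to −0.183). The hypothesis that accessibility rose over whole stretches stays open. Over all positions, higher shared regions had a gained region within 50 kb 12.7 percentage points more often than lower ones (interval 8.50 to 16.7), which was at first read in its favour. With the same distance kept from the contig start and last region, a restriction chosen after that value was seen and met by 779 of the 882 higher and 564 of the 1018 lower regions, the difference was 2.65 points (interval −2.06 to 7.80).

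Lost regions, and shared regions called lower after centring, were concentrated on contigs that held few regions. The lengths of the contigs were not used here. Contigs with at most 2 regions held 34.6% of the lower shared regions, 3.63% of the higher and 5.19% of the others. After centring on the median height, the 971 shared regions on such contigs had a median log2 change of −0.347, and 81.3% were lower, against −0.0091 and 51.5% for shared regions elsewhere. Scaled by depth alone, the medians were −0.073 on such contigs, where 57.9% were lower, and 0.27 elsewhere, where 14.5% were lower. A candidate explanation is a kind of sequence, such as repeats left on contigs of their own, that took a larger share of tags in the control libraries. It stays open, since a share of tags is measured on the depth scale, where the shift was small, and the 971 include the 352 lower regions from which the hypothesis came. Whether it reflects the samples' preparation or the treatment was not tested, and with those contigs left out 786 shared regions were higher and 734 lower.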
